A study of Arabidopsis thaliana with 6 samples.

How the data were processed

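Poly-A RNA from peeled leaf epidermis of Arabidopsis thaliana, guard cells included, was measured in 6 libraries, 3 biological replicates in each of 2 groups. Per the labels, one group is the phot1 phot2 double mutant in a gl1 background, which lacks the blue light receptors phototropin 1 and 2. The other carries in addition SOC1 fused to green fluorescent protein under the promoter of GC1, a gene expressed in guard cells (SOC1-GFP below). SOC1 is a MADS-box transcription factor best known for promoting flowering. Plants grew at 22 °C in 16 h light and 8 h dark. The labels disagree on age, with 3 weeks in the sample fields and 4 to 5 weeks in the series design. Libraries were made from 4 µg of total RNA and sequenced on an Ion PGM with 318 chips.

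The deposited files hold 1 line per aligned read, with the name of a TAIR10 transcript model and the start and end of the aligned span (counts per gene were not used here). Per the labels the build is TAIR10. The aligner and its settings are not given in the sources used here. The files have no strand, read name or mapping quality, so reads from a gene and from an antisense partner cannot be told apart, and reads shared by near-identical copies such as LHCB1.1 and LHCB1.2 are uncertain.

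Reads were counted per gene by summing the transcript models of each gene. In genes with reads on the first and second model, 2.73% to 4.25% of the spans of the smaller model were also found on the other, so few reads can have been entered for both at the same positions. Reads entered at shifted positions, on models with different starts, would be missed by this check. The files list 28220 genes, of which 210 lie in the organelles and were left out, and 27620 identifiers matched the reference table of TAIR10.1, from which names were taken. The 600 that did not match hold 0.678% of the reads. Totals ran from 2546482 to 4485097 reads. Mean aligned spans ran from 63.0 to 107.4 bases. The floor of 3 counts used below covers counting error only, since amplified reads are not independent molecules.

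The design fixed beforehand named a test for deposited counts and, for files with 1 line per read, limma voom, and the latter was used because the files hold aligned reads. Genes needed 10 reads, scaled to the median library, in 3 libraries and 15 reads in all, which left 17671. Library factors were of the TMM type, with 30% of log ratios and 5% of mean levels trimmed. limma 3.58.1 in R 4.3.3 was run with robust empirical Bayes moderation and Benjamini-Hochberg adjustment, two-sided, with a threshold of 0.05. Log2 fold changes are SOC1-GFP minus control, with standard errors. Levels are CPM after these factors, given as mean ± SD with 3 libraries per group. For single values an exact permutation test was used, two-sided and without regard to replicate number, in which 3 against 3 libraries cannot go below p = 0.1.

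The groups, the comparison, 21 gene lists, the rule for named genes and most of the other settings were chosen before the data were examined. The rule names SOC1, PHOT1, PHOT2, GL1 and GC1, then 9 genes of light-driven stomatal opening, then genes past the threshold, or where fewer than 10 pass in a direction the genes of smallest unadjusted p up to 10, and in each list the 2 members of smallest unadjusted p where none passes. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

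Whether replicate numbers pair the libraries was checked before calls were compared. Deviations from the group means correlated at 0.714, 0.495 and 0.534 between libraries with the same number, and per the file names those libraries were run within a day of each other in June and July 2014, so the numbers pair the libraries. The fit with the replicate number as a block was among the settings chosen then.

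The fits were tested on simulated data with 200 of 17671 genes changed, the same spread for every gene and the same fold in each pair. With the pair differences and the spread within pairs of these libraries, the fit without the block recovered 0% of genes changed 2-fold and 0% of those changed 4-fold, and the fit with the replicate block recovered 41% and 93%, with 4 false calls among 138. At a low spread without pair differences the fit without the block recovered 79% and 94%, and at the spread within groups of these libraries 17% and 89%, with 9 false calls among 115. In simulated data without pair differences or correlation between genes, a planted list was recovered and 1 of 50 unchanged lists passed. The estimated correlation within the lists tested here reached 0.9, so this gives no rate of false list calls for these libraries.

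Positions along transcripts were used for SOC1, as planned, and for a scan of 100-base windows chosen after the data were seen. A window was kept where the lowest library of one group had at least 2.5 reads for each 1e6 in the library and more than 4 times the sum of 0.5 and the highest library of the other group. Simulated reads, well above the cutoff, were added to the real counts in 200 windows with next to no reads, and all 200 were recovered. This does not cover windows near the cutoff or in well covered transcripts. The coding window of SOC1 spans bases 493 to 1026 and the 3′ window starts at base 1138. Up to 111 bases of the 5′ end of the 1431-base reference transcript may be missing from the model in the files, so the windows leave a gap of that length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.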

Results

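Gene expression was compared between leaf epidermis of the phot1 phot2 double mutant (control) and of the same mutant expressing SOC1-GFP from a guard cell promoter, with 3 libraries per group. The comparison asks which transcripts differ when SOC1 is supplied in guard cells of plants without phototropins. The control libraries held 4207812, 3848791 and 4007558 reads and the SOC1-GFP libraries 2546482, 3361762 and 4485097, for replicates 1, 2 and 3.

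SOC1 reads from the coding part of the transcript were higher in the SOC1-GFP libraries. SOC1 (AT2G45660) lies on chromosome 2 from 18807505 to 18811125 in TAIR10.1, on the minus strand, with 8 exons. In the coding window the level was 93.64 ± 14.997 CPM in SOC1-GFP and 43.14 ± 11.237 CPM in controls, a ratio of 2.17, with each SOC1-GFP library above each control library. The exact permutation p, which ignores the pairs, was 0.1, the smallest that 3 against 3 libraries allow. Levels in the 3′ untranslated window were 10.1 ± 2.45 and 13.57 ± 11.997 CPM (exact permutation p = 0.9), and in the 5′ window 6.22 ± 1.65 and 9.12 ± 3.36 CPM (exact permutation p = 0.2). The ratio of coding to 3′ reads was 9.78 ± 3.15 against 4.63 ± 2.46 (exact permutation p = 0.1). The groups were only narrowly apart, with 6.32 in SOC1-GFP replicate 3 and 6.25 in control replicate 2, from 59 and 20 reads in the 3′ window. Over the whole transcript SOC1 did not pass the test, with a log2 fold change of 0.62 ± 0.40 (limma adjusted p = 0.9999).

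**Figure D1:**
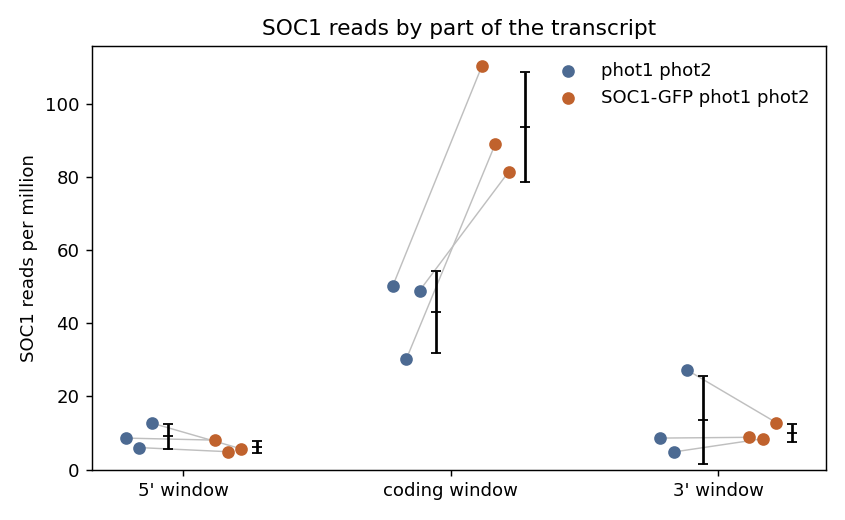
SOC1 CPM (vertical axis) in the 5′, coding and 3′ windows of the transcript, for control (blue) and SOC1-GFP (orange) libraries. Grey lines join libraries with the same replicate number and black bars give mean ± SD. In the coding window the SOC1-GFP libraries lie between 81.4 and 110.4, above the controls at 30.2 to 50.3.

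PHOT1, PHOT2 and GC1 did not pass the test, and GL1 had too few reads to be tested. PHOT1 had 109.1 ± 10.9 CPM in controls and 118.3 ± 23.1 in SOC1-GFP, and PHOT2 had 179.2 ± 84.4 and 140.3 ± 41.3. Both groups carry the same phototropin mutations, so these levels do not check the labels. GL1, a trichome regulator, had 2, 0 and 1 reads in controls and 2, 1 and 0 in SOC1-GFP, at or under the floor of 3 counts in each library. GC1, whose promoter drives the transgene, had 91.8 ± 120.0 CPM in controls and 227.1 ± 105.7 in SOC1-GFP, a log2 difference of 2.09 ± 1.09. It was higher in 3 of 3 pairs.

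The genes of light-driven stomatal opening did not pass the test one by one, and as a list they lay above other genes. BLUS1, a kinase acting downstream of phototropins, differed by 1.37 ± 0.72 and was higher in 3 of 3 pairs, with 0.74 without control replicate 3 and 2.11 without control replicate 1. Among the plasma membrane proton pumps that power opening, AHA5 differed by 0.79 ± 0.38 and AHA2 by 0.47 ± 0.34, with no overlap between groups, and AHA1 by 0.22 ± 0.45. The potassium channel genes KAT2, KAT1 and AKT1 differed by 0.79 ± 0.44, 0.03 ± 0.28 and -0.06 ± 0.91. The KAT1 difference turned to -0.01 with median ratio factors, and that of AKT1 to 0.11 with total count scaling. HT1, a kinase of the carbon dioxide response, and PATROL1, which moves proton pumps to the membrane, differed by 0.51 ± 0.43 and 0.41 ± 0.31. Each of these 9 genes had a limma adjusted p of 0.9999. Over the 21 members of the list, 17 differences were positive, with a mean of 0.28 (camera adjusted p = 0.00678). That call was lost with adjusted p = 0.61 with an estimated correlation. The mean was 0.09 without SOC1-GFP replicate 1, which also ended the call, and 4 members are shared with the guard cell list.

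No single gene passed the threshold between the groups. The limma voom test called 0 genes higher and 0 lower among 17671, and 215 genes had an unadjusted p under 0.05, 120 of them higher. Simulated data with the pair differences of these libraries and 200 changed genes gave 157 by the same fit. With the replicate number as a block limma again called 0 genes, with a smallest adjusted p of 0.1746 and 1146 genes at an unadjusted p under 0.05. Groups did not overlap for 5.6% of genes, where chance gives 10% for libraries that are not paired. In simulated data with the pair differences of these libraries the fit without the block recovered no changed gene, so its count of 0 does not show that genes did not differ. The fit with the replicate block recovered 41% of genes changed 2-fold and 93% of those changed 4-fold. Its count of 0 therefore argues against many 4-fold changes only in genes of the spread simulated. Genes of wider spread are not covered, such as COR15A at -3.25 ± 0.72 with the block (limma adjusted p = 0.4658).

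Among the genes of smallest unadjusted p that were higher in SOC1-GFP, none of them past the threshold, AT1G22680 had 47, 22 and 56 reads against 0, 4 and 1 in controls, a log2 difference of 4.76 ± 0.85. It lies beside GC1 on chromosome 1, from 8024967 to 8026356 on the minus strand in TAIR10.1, and 2 of its 125 reads in the SOC1-GFP libraries lay past the coding part. AT3G17900 differed by 1.21 ± 0.25, RPF1 by 1.51 ± 0.36, UGT76B1, which glycosylates an activator of salicylic acid defence, by 2.13 ± 0.54, the receptor-like kinase gene CRK31 by 1.54 ± 0.39 and AT4G19645 by 1.35 ± 0.37. The other 4 were AT1G52990, AT3G58370, AT3G14160 and AHBP-1B (AT5G06950). Their differences of 4.81 ± 1.03, 5.89 ± 1.48, 1.78 ± 0.48 and 2.87 ± 0.79 came from reads in narrow windows, outside which they were 0.61, 0.06, 0.13 and 0.14 (mean CPM with 0.5 added). Outside the windows AT1G52990 held 4 reads in controls and 9 in SOC1-GFP, and AT3G58370 4 and 4, too few to tell.

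**Figure D2:**
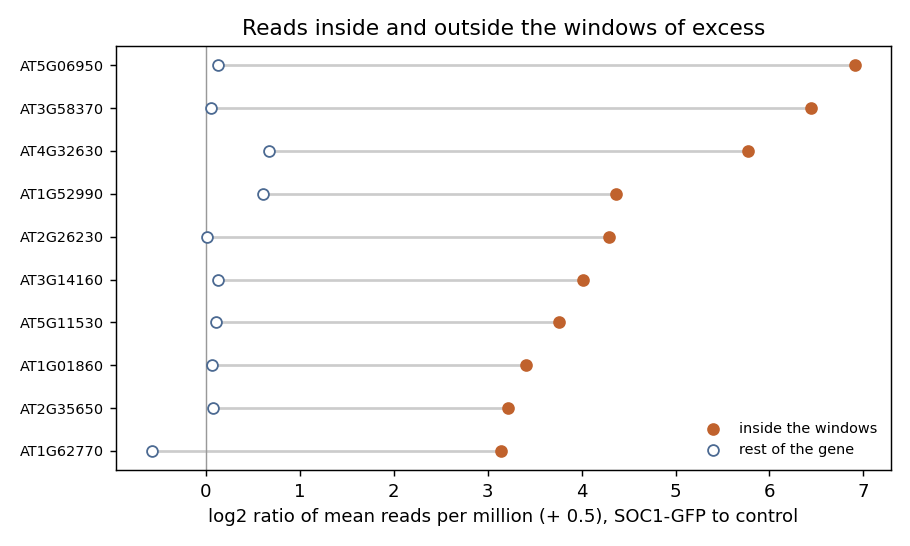
Log2 difference, SOC1-GFP minus control, of reads inside narrow windows and in the rest of the gene, for the 10 genes with such windows, which were chosen for their excess. Inside the windows the differences were 3.14 to 6.91 and in the rest of the gene -0.57 to 0.68.

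Genes of smallest unadjusted p that were lower in SOC1-GFP, also not past the threshold, included the floral repressor MAF5, at 6.06 ± 2.12 CPM against 19.8 ± 4.88 (log2 -1.65 ± 0.36), and the cold-induced chloroplast protein gene COR15A, at 15.6 ± 10.4 CPM against 144.7 ± 94.2 (log2 -3.15 ± 0.73). The remaining 8 were AT5G66052 at -1.54 ± 0.41, CYP96A7 at -1.31 ± 0.40, the signal recognition particle RNA gene AT7SL-1 at -1.23 ± 0.36, ELI3-1 at -1.15 ± 0.35, AT5G01700 at -1.08 ± 0.33, HBP1 at -1.04 ± 0.29, AT1G75960 at -1.01 ± 0.28 (-0.21 with spans of at least 30 bases) and AT1G07440 at -0.96 ± 0.27. In each of these 10 genes every SOC1-GFP library lay below every control library. CYP96A7 fell below the count filter with identical spans counted once and with spans of at least 30 bases.

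Of the 21 lists, 12 passed camera at the preset correlation, 6 higher and 6 lower, and none passed with an estimated correlation or by fry. Of these 12, in fits without the block, the cold list alone stayed past the threshold without control replicate 3 (-0.59, adjusted p = 0.0395), the cold, abscisic acid induced and flowering lists did so without SOC1-GFP replicate 1, and the cold and guard cell lists without both replicate 3 libraries. Leaving out both replicate 3 libraries with the block ended only 3 of the 12 calls. With the replicate block, members past the threshold over the list alone numbered 2 in the pavement cell list, 1 in the vascular, 1 in the flowering, 2 in the SOC1 target and 1 in the wounding list, each with 0 without the block. Guard cell markers had the largest mean among the higher lists, 0.71, with 14 of 15 members positive (camera adjusted p = 1.26e-05, and adjusted p = 0.61 with an estimated correlation). FAMA, which sets guard cell identity, differed by 1.48 ± 0.53, and the anion channel gene SLAC1 by 0.93 ± 0.40. Adjusted over the list alone, 0 members passed without the block and 7 with the replicate block. The list mean dropped to 0.31 without control replicate 3 (adjusted p = 0.0864) and to 0.32 without SOC1-GFP replicate 1 (adjusted p = 0.122), which ended the call in both cases. Both fits kept the other library of the pair, so differences between pairs enter these means. Pairs 1, 2 and 3 differed by 0.615, 0.286 and 1.214. Without both libraries of replicate 1, 2 or 3 the mean was 0.735, 0.933 and 0.459, and the call stayed.

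Stomatal lineage genes had a mean of 0.43 with 11 of 13 positive (camera adjusted p = 0.00678, and adjusted p = 0.61 with an estimated correlation), among them ICE1 at 0.54 ± 0.25. The mean was 0.19 without control replicate 3 and 0.69 without control replicate 1. Adjusted over the list alone, 0 passed without the block and 3 with it. Markers of other cell types moved with the guard cell list. Pavement cell and cuticle markers had a mean of 0.44 with 16 of 17 positive (camera adjusted p = 0.00678, and adjusted p = 0.812 with an estimated correlation), with the wax genes CER4 at 1.70 ± 0.49 (2.89 with spans of at least 30 bases) and CER2 at 1.40 ± 0.98. That mean turned to -0.04 without control replicate 3 and to -0.12 without SOC1-GFP replicate 1. Vascular markers had a mean of 0.43 with 10 of 13 positive (camera adjusted p = 0.00651, and adjusted p = 0.61 with an estimated correlation), including SEOR1 at 1.11 ± 0.61 and FTIP1 at 0.46 ± 0.26 (0.25 with quality weights). That mean was 0.05 without control replicate 3 and 0.64 without SOC1-GFP replicate 3. Dividing cell markers had a mean of 0.52 with 10 of 10 positive (camera adjusted p = 0.0357, and adjusted p = 0.812 with an estimated correlation), with the cyclin genes CYCA1;1 at 0.83 ± 0.74 and CYCB1;2 at 1.06 ± 1.04. The mean was -0.13 without control replicate 3. Mesophyll and photosynthesis markers did not pass, with a mean of -0.18 (camera adjusted p = 0.165), and the Calvin cycle genes SBPASE and PRK differed by -0.45 ± 0.66 and -0.37 ± 0.62. That list passed in opposite directions without control replicate 1 (0.53) and without SOC1-GFP replicate 1 (-0.64), each with a camera adjusted p under 0.05. It passed in 7 of 25 other settings, with a smallest adjusted p of 2.67e-13 with the replicate block without both replicate 3 libraries, and with all libraries in under total count scaling (adjusted p = 0.021). Under that scaling the list mean was 0.005, below the median of 0.183 over all genes.

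Cold response genes of the CBF regulon had the lowest mean of any list, -1.15, with 13 of 13 members negative (camera adjusted p = 1.52e-07, and adjusted p = 0.61 with an estimated correlation). COR15B differed by -2.30 ± 0.88 and CBF1, a transcription factor of the cold response, by -1.04 ± 0.73, lower in 3 of 3 pairs, and by -0.29 without SOC1-GFP replicate 1 and -1.48 without control replicate 1. Adjusted over the list alone, 1 member passed, COR15A, and 2 passed with the replicate block. Pairs 1, 2 and 3 differed by -0.33, -0.73 and -2.32, and the mean was -0.54 without both replicate 3 libraries (adjusted p = 0.0112) and -1.82 without control replicate 1. Abscisic acid and drought induced genes, which share 7 members with that list, had a mean of -0.91 with 12 of 13 negative (camera adjusted p = 1.26e-05, and adjusted p = 0.61 with an estimated correlation), and NCED3, an enzyme of abscisic acid synthesis, differed by -0.92 ± 0.36. Adjusted over the list alone, 1 passed, again COR15A. The mean ran from -1.43 without control replicate 1 to -0.29 without both replicate 3 libraries, where the call ended without the block and stayed with it. The list passed in 21 of 25 other settings.

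Wounding and jasmonate genes had a mean of -0.81 with 16 of 18 negative (camera adjusted p = 8.67e-05, and adjusted p = 0.665 with an estimated correlation), with VSP2 at -2.50 ± 1.05 and AOC2 at -1.42 ± 0.75. Without control replicate 3 the mean turned to 0.09, and without control replicate 1 it was -1.50. Touch and early stress genes had a mean of -0.30 with 13 of 14 negative (camera adjusted p = 0.0468, and adjusted p = 0.812 with an estimated correlation), with TCH2 at -0.31 ± 0.34 and ZAT10 at -0.65 ± 0.74, and a mean of 0.34 without SOC1-GFP replicate 1 and -0.76 without SOC1-GFP replicate 2. With all libraries in, the touch call also ended with limma trend, median ratio factors, the stricter filter, identical spans counted once, organelle genes kept in, spans of at least 30 bases and quality weights. Flowering time and floral MADS genes had a mean of -0.23 with 18 of 27 negative (camera adjusted p = 0.00678, and adjusted p = 0.61 with an estimated correlation), with FD, a partner of the florigen FT, at -1.04 ± 0.39 and MAF5 as above. That mean ran from -0.46 without both replicate 1 libraries to -0.13 without both replicate 3 libraries, and was -0.06 under total count scaling, which moved the median of all genes to 0.18. Published direct SOC1 targets, which share 10 members with the flowering list and 3 with the cold list, had a mean of -0.33 with 11 of 15 negative (camera adjusted p = 0.0295, and adjusted p = 0.61 with an estimated correlation), with LFY at -0.92 ± 0.45. LFY had 83, 345 and 175 reads in controls and 48, 95 and 128 in SOC1-GFP. It fell below the count filter with identical spans counted once and with spans of at least 30 bases. In most libraries most of its reads were therefore short and repeated spans, and whether they come from LFY was not tested. LFY counts in both the target and the flowering list. The mean of the target list was -0.15 without control replicate 3, which ended the call.

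With all libraries in, salicylic acid and pathogen response genes passed with the replicate block and not without it. Their mean was 0.48 with 16 of 19 positive (camera adjusted p = 0.108), and 0.53 with the block (camera adjusted p = 5.47e-07, and adjusted p = 0.493 with an estimated correlation). Adjusted over the list alone, 0 members passed without the block and 8 with it. Without the block the mean ran from -0.32 when control replicate 1 was left out to 1.42 when SOC1-GFP replicate 1 was left out (adjusted p = 4.75e-10), and 4 of the 9 fits that leave out libraries passed. Both of these extremes come from fits that kept the other replicate 1 library. Pairs 1, 2 and 3 differed by 0.162, 0.952 and 0.383. FMO1, needed for systemic acquired resistance, differed by 2.26 ± 1.63 without the block and 2.12 ± 0.30 with it, and was higher in 3 of 3 pairs. The defensin gene PDF1.2 differed by -2.16 ± 1.27 without the block and -2.55 ± 0.58 with it, and was lower in 3 of 3 pairs. Without the block, FMO1 ran from 0.85 without control replicate 1 to 3.46 without SOC1-GFP replicate 1, and PDF1.2 from -3.08 without control replicate 1 to -1.05 without control replicate 3.

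**Figure D3:**
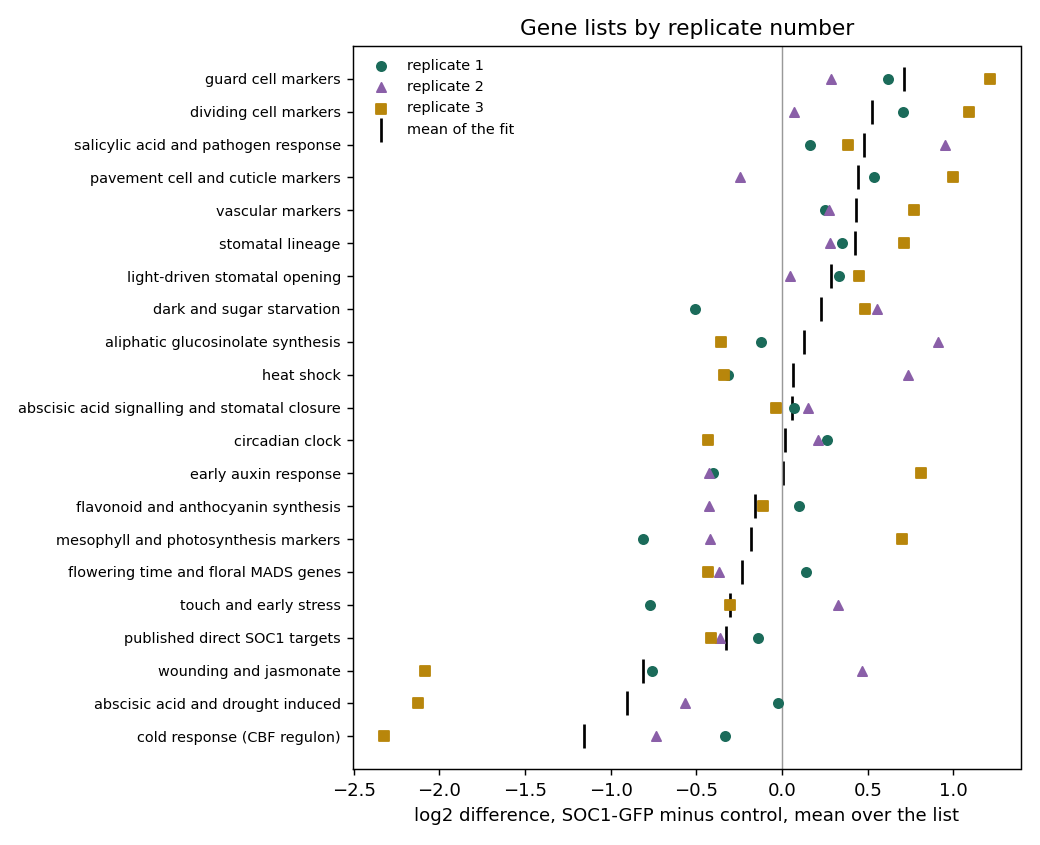
Mean log2 difference over each gene list (horizontal axis), SOC1-GFP minus control, for each of the 21 lists (vertical axis). Coloured symbols are the pairs of replicates 1, 2 and 3 and black ticks the mean of the fit without the block. Pair 3 lies farthest from 0 in the cold list, at -2.32.

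With all libraries in, the remaining 7 lists did not pass camera with or without the block. With libraries left out, with or without the replicate block, glucosinolate synthesis passed in 4 settings (smallest adjusted p = 0.000789), dark and sugar starvation in 2 (0.00965), heat shock in 1 (0.0264) and flavonoid synthesis in 1 (0.0479). Abscisic acid signalling and stomatal closure had a mean of 0.06 (adjusted p = 0.741) with the potassium channel gene GORK at 0.94 ± 0.46. Heat shock had 0.07 (adjusted p = 0.656) with HSP70B at 0.34 ± 0.31 and HSP101 at 0.33 ± 0.47, and dark and sugar starvation 0.23 (adjusted p = 0.493) with DIN9 at 1.04 ± 0.43 and ASN1 at -0.49 ± 0.50. Aliphatic glucosinolate synthesis had a mean of 0.13 (adjusted p = 0.402) with MYB29 at 0.63 ± 0.33 and FMOGS-OX1 at 0.33 ± 0.55, and flavonoid and anthocyanin synthesis -0.16 (adjusted p = 0.656) with TT7 at -1.10 ± 0.57 (-0.54 with quality weights) and CHI at 0.61 ± 0.40. The circadian clock list had a mean of 0.02 and a median of -0.02, and camera ranked it lower (adjusted p = 0.656), with LKP2 at -0.32 ± 0.26 and RVE2 at -0.89 ± 0.86. Early auxin response had a mean of 0.00 that camera also ranked lower (adjusted p = 0.871), with GH3.5 at -0.66 ± 0.54 and IAA19 at 0.36 ± 0.32.

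Libraries mostly resembled their replicate number more than their group. Across genes, log2 levels correlated at 0.945, 0.95 and 0.92 between libraries with the same number and at 0.798 to 0.922 within groups. The first principal component held 53.6% of the variance and the second 23.5%. The 10 most abundant genes took 17.3% of reads in control replicate 1 and 5.88% to 12.04% in the other libraries.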

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

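The tests of read position, aligned span, spread among list members and other splits of the libraries were chosen only after the results were seen, while leaving out libraries was planned.

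Positions of reads, which the counts per gene do not use, differed between the groups in a scan for windows where every library of one group lies above the other: in 13 windows of 10 genes, found by a scan of 503557 windows, the SOC1-GFP libraries held 274.44 ± 274.48 CPM and the controls 2.9 ± 0.97, a gap that the choice of windows fixes, and 0 windows went the other way. Reads of these genes outside the windows had a median log2 difference of 0.096 (-0.57 to 0.68), against 4.15 inside. They argue against higher expression of the genes with at least 51 such reads in each group, at 0.02 to 0.14. In AT1G52990, AT3G58370, AT4G32630 and AT1G62770 such reads were too few to tell. They numbered 4, 4, 9 and 19 in controls and 9, 4, 18 and 9 in SOC1-GFP. In each of the 10 genes at least 90.0% of the reads inside had aligned spans under 30 bases, against 5.2% to 15.83% in the whole SOC1-GFP libraries, as partial alignments of reads from elsewhere would give. Reads of the transgene as their source cannot be told apart from other differences between the groups, since the construct sequence was not used and the gap between the lowest SOC1-GFP library at 61.58 CPM and the highest control at 3.87 follows from how windows were chosen. The real split gave 13 windows and the highest other split 12, and of the 10 splits 1, the real one, gave as many, too few splits for a share under 0.05.

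Reads of AT1G22680, whose start lies 770 bases from that of GC1 on the other strand, were nearly limited to the SOC1-GFP libraries. With spans of at least 30 bases there were 115 reads in the SOC1-GFP libraries and 0 in the controls, at least 39.9-fold more against a floor of 3 counts over the control group. Transcription of the whole gene is argued against by the 2 of 125 reads in the last part of the transcript, a share at percentile 1.1 of 6348 transcripts of similar length, and at percentiles 0.28 to 0.84 under the other 3 choices of spans and transcripts tried. Short partial alignments are argued against too, since 8.0% of its reads had spans under 30 bases. A piece of the gene carried with the GC1 promoter may be the source, as 88.7% of its longer spans lay in the part of the transcript that faces GC1, but the extent of the promoter was not used, so this cannot be told apart from a shortened transcript of the gene itself.

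Guard cell markers had a list mean of 0.71, a call lost with adjusted p = 0.61 with an estimated correlation and 0.905 by fry. With the replicate block the 15 members spread beyond their standard errors, with KAT1 at 0.01 ± 0.25 and FAMA at 1.43 ± 0.24. The scaled Cochran Q was 42.4 (chi-squared approximation over n = 15 members with limma standard errors from the 3 pairs, p = 0.000108). This spread cannot decide whether a larger share of guard cells is the whole cause. Equal shifts would follow only if all members were equally limited to guard cells, which was not tested. Of the 15, 10 are also in the lists on stomatal opening, stomatal closure or stomatal lineage, which does not bear on this. GC1 and KAT1 differed by unequal factors among the control libraries alone, as given below. Control replicate 3 alone may carry the call, as the adjusted p was 0.0864 without it, but it was 0.0112 without both replicate 3 libraries and 1.97e-09 to 0.905 over all settings run, so this cannot be told apart from a difference carried by more pairs. Of the 10 splits, which are too few for a share under 0.05, 4 gave an absolute list mean as large, with 0.71 for the real one, 1.06 for the highest other and 0.51 for the highest of the 3 others that part every pair, and an effect of SOC1 on guard cell genes stays open, untested.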

How the results depend on the processing

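Spans of at least 30 bases, sample quality weights, the SOC1 windows with the replicate block, and the replicate block without both replicate 3 libraries were chosen after seeing the data. The other settings were planned. Where a value changed, the cause was not tested.

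The count of genes past the threshold stayed at 0 in both directions under every other setting run, with 85 to 448 genes at an unadjusted p under 0.05 in limma when libraries were left out. The exception was the replicate block with spans of at least 30 bases, which called 1 gene higher, AT1G22680 (limma adjusted p = 0.01737, 16449 genes tested). Its adjusted p ranged from 0.01737 to 1 over the settings run. With the replicate block alone 1146 genes had an unadjusted p under 0.05, against 215 without it, and 727 without a filter, 551 with quality weights, 944 with the replicate block and spans of at least 30 bases, and 1492 with the replicate block without both replicate 3 libraries.

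Lists past the threshold numbered 12, and 13 with the replicate block, whose added call is the salicylic acid list. They numbered 0 with an estimated correlation, 0 by fry and 6 with quality weights, and 4 to 13 when libraries were left out. Without control replicate 3 there were 4, of which 1 is among the 12, without both replicate 3 libraries 4, of which 2 are, and without SOC1-GFP replicate 1 there were 7, of which 3 are. These 3 fits had no block. Leaving out both replicate 3 libraries with the replicate block ended 3 of the 12 calls and gained 4 others. Without a filter 8 passed and with spans of at least 30 bases 8, each setting ending 4 of the 12 calls. They numbered 11 with limma trend, 11 with median ratio factors and 11 with organelle genes kept in, each ending the touch call, 10 with the stricter filter, which ended the touch and dividing cell calls, and 10 with identical spans counted once, which ended the touch and SOC1 target calls. Total count scaling ended the dividing cell call and gained the mesophyll list. With all libraries in, the replicate block changed no other call.

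SOC1 differed by 0.30 to 0.94 when libraries were left out, by 0.65 with the replicate block and by 1.15 in the coding window alone. It turned to -0.28 in the untranslated windows alone and to -0.36 there with the replicate block, windows that hold no coding sequence.

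The circadian clock list, near 0, turned to -0.024 with the replicate block, -0.016 with median ratio factors, -0.047 without a filter, -0.031 with identical spans counted once, -0.059 with spans of at least 30 bases and -0.063 with the replicate block and such spans. The early auxin list turned to -0.096 with the replicate block, -0.019 with limma trend, -0.024 with median ratio factors, -0.103 without a filter and -0.362 with the replicate block without both replicate 3 libraries. KAT1 turned to -0.0053 with median ratio factors and -0.0411 without a filter. Total count scaling moved the median of all genes from 0.019 to 0.183, and took the flowering list to -0.063. It turned AKT1 to 0.1105 and moved the mesophyll list mean to 0.005, with a camera adjusted p of 0.021. That mean still lies below the median of 0.183, so the list did not move above other genes. The replicate block without both replicate 3 libraries turned AKT1 to 0.7248. Quality weights turned AHA1 to -0.1069, KAT1 to -0.0587, ASN1 to 0.0843, the mesophyll list to 0.31, the dividing cell list to -0.118 and the flavonoid list to 0.363.

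Leaving out libraries gave these ranges for results that changed sign: PHOT1 -0.1431 to 0.3068, PHOT2 -0.8219 to 0.0818, KAT1 -0.1724 to 0.2488, AKT1 -0.8887 to 0.5681, SBPASE -1.0101 to 0.1094, PRK -0.7531 to 0.1717, CYCB1;2 -0.0862 to 1.7874, RVE2 -1.4854 to 0.0201, ZAT10 -1.0664 to 0.0297 and FMOGS-OX1 -0.2727 to 0.838. For lists they were -0.121 to 0.879 for pavement cells, -0.643 to 0.525 for mesophyll, -0.126 to 1.018 for dividing cells, -0.031 to 0.201 for abscisic acid signalling, -0.118 to 0.223 for the clock, -1.5 to 0.093 for wounding, -0.755 to 0.344 for touch, -0.316 to 1.42 for salicylic acid, -0.295 to 0.426 for heat shock, -0.06 to 0.576 for dark, -0.375 to 0.182 for auxin, -0.249 to 0.42 for glucosinolates and -0.614 to 0.414 for flavonoids. The cold list kept its sign throughout, at -1.818 to -0.541. Fits that leave out a single library keep its partner, so differences between pairs enter these ranges. Over all settings run, other named genes that moved by over 1.5 times ranged as follows: AHA1 -0.1069 to 0.4327, AHA5 0.3768 to 1.008, AHBP-1B 0.036 to 3.799, AKT1 -0.8887 to 0.7248, AOC2 -2.062 to -0.5067, ASN1 -0.9774 to 0.0843, AT1G75960 -1.273 to -0.2117, AT3G14160 0.1262 to 2.111, BLUS1 0.738 to 2.114, CBF1 -1.481 to -0.2933, CER2 0.4156 to 2.221, CER4 1.224 to 2.889, CHI 0.3012 to 0.8376, COR15B -3.757 to -1.019, CYCA1;1 0.275 to 1.272, DIN9 0.5861 to 1.41, FMO1 0.8502 to 3.457, FTIP1 0.2482 to 0.6327, GC1 1.2 to 3.236, GH3.5 -1.131 to -0.3045, GORK 0.4881 to 1.339, HSP101 0.0244 to 0.6816, HSP70B 0.1093 to 0.4931, HT1 0.2265 to 0.8868, IAA19 0.1178 to 0.5243, KAT1 -0.1724 to 0.4566, KAT2 0.3618 to 1.119, LFY -1.375 to -0.5029, LKP2 -0.4357 to -0.1593, MYB29 0.3163 to 1.028, NCED3 -1.284 to -0.5994, PATROL1 0.2297 to 0.6457, PDF1.2 -3.079 to -1.05, PRK -0.7645 to 0.1717, RVE2 -1.926 to 0.0201, SEOR1 0.4369 to 1.442, SLAC1 0.5113 to 1.265, TCH2 -0.5066 to -0.1212, TT7 -1.627 to -0.5368 and VSP2 -3.331 to -1.259.

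Not run were the settings on strand, mapping quality and introns, since the lines give transcript positions alone, and the other count test, which was planned for deposited counts. Depth of 2546482 to 4485097 reads limits genes of few reads. GL1 had few reads too, but the labels give a gl1 background, so depth cannot be told apart from genotype there.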

Other observations

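Among the control libraries, GC1 differed 13.2-fold between the highest and lowest and KAT1 1.12-fold, both in the guard cell list. FMO1 had 1, 56 and 37 reads in control replicates 1, 2 and 3 and 7, 164 and 249 in SOC1-GFP.

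The tests of other splits were chosen only after the result was seen. For the number of genes past the threshold, 10 of the 10 splits gave as many as the real 0, which any split would, and the highest other was also 0, so this comparison says nothing on chance. limma gave 215 genes at an unadjusted p under 0.05 for the real split and 2950 for the highest other, which sets control replicates 1 and 2 and SOC1-GFP replicate 1 against the rest and points to a structure of the libraries, as these 3 were the lowest on the first principal component. For lists, 3 of the 10 splits gave as many as the real 12, and the highest other gave 14. Among splits that part every pair, the other 3 gave at most 10 lists, and with the replicate block at most 10 against 13 and 558 to 1034 unadjusted genes against 1146. The splits are too few for a share under 0.05.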
